A study of Mus musculus with 12 samples.

How the data were processed

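RNA sequencing was carried out on primordial germ cells, the embryonic precursors of eggs and sperm, from female mouse embryos at embryonic day 14.5. Per the labels' protocols, cells were sorted by an Oct4-GFP reporter, total RNA was extracted from 5000 cells with a Zymo Research column kit, mRNA was isolated on oligo d(T) beads, and libraries were made with an NEB kit. The 12 libraries fell into 4 groups of 3. WT was wild type, HxD carried a catalytically dead Tet1, V carried a Tet1 mutant described as stalling at 5-hydroxymethylcytosine, and KO was the Tet1 knockout. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 libraries of a group came from separate embryos or litters, so p-values measure the spread between these libraries, which may be partly technical.

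The authors deposited 1 table of whole-number counts per gene, not normalized, with 35976 gene symbols and 12 columns. Per the submitters' processing notes, FastQC, Trim Galore 0.6.7, STAR 2.7.10b, SAMtools 1.9 and featureCounts 2.0.3 were used. Those notes name the builds GRCm39 and mm10 without saying which was used for what, so no coordinates are printed. The annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Genes with near-identical copies (Tuba3a, Rhox6) and genes that overlap others are therefore uncertain, and reads of a gene and its antisense partner could not be told apart. The mitochondrial genes COX2, COX3, ATP6 and ATP8 were listed at 0 in all 12 libraries although other mitochondrial genes were abundant, so a 0 in this table can reflect the counting. Older symbols were matched to the list members by hand: Meiosin is Gm4969 and Six6os1 is 4930447C04Rik.

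Total counts per library ranged from 18471158 to 29495313. A count was present for 22037 genes in at least 1 library. The libraries differed in how many genes they captured, from 12568 genes with a count in KO3 to 17614 in HxD3. Among 2938 genes with a mean of 1 to 5 CPM (counts scaled to a common library total), the share at 0 was 43.7% in HxD1, 45.9% in KO3, 27.3% in KO1 and 24.5% in V2. It was 16.2%, 13.2% and 20.8% in WT1, WT2 and WT3, and between 1.80% and 9.94% in the other libraries. No molecular identifiers were described, so reads are not independent molecules, and floors of 3 counts cover counting error only. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 30.2, so no library was the same counts deposited again; repeats amplified separately from the same sample could exceed this value too and were not excluded.

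The main test was edgeR 4.0.16 (quasi-likelihood F test, two-sided, in R 4.3.3) on the counts as deposited. It used TMM normalization, default filterByExpr, 1 fit of all 12 libraries with group as the only term, and Benjamini-Hochberg adjustment over the 16166 genes kept, called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the estimate divided by the square root of F. CPM values are normalized by TMM and given as mean ± SD with n = 3. Genes were compared in 6 contrasts, each mutant against WT and each pair of mutants. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. On data simulated for KO vs WT over 16166 genes, edgeR recovered 46% of the genes changed by 1 on the log2 scale and 82% of those changed by 2, with 11 false calls among 146. Over 15710 genes DESeq2 recovered 48% and 86% with 60 false calls among 202, and it called 27 genes in a comparison simulated without change, where edgeR called 0. The changed genes, 100 of each size, were drawn only from genes with a mean of at least 5 CPM. Recovery of genes of few counts was therefore not measured. The simulation was run once and did not model the loss of rare molecules, so its rates may be better than those on these libraries.

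Of 21 gene lists fixed in advance, 19 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each test was repeated with an estimated correlation. Lists share members: 7 genes are in both the meiotic list and the list of germline genes methylated in somatic cells, and 10 are in both the latter and the piRNA list. The list of 2-cell stage genes had 1 tested member and the Y-linked list none, so neither was tested. Gene positions for the test by chromosome came from a RefSeq table of assembly GRCm38.p6, used only for chromosome and neighbourhood; 93.3% of the tested genes matched it by symbol.

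Genes named in the text were chosen by a rule. In each comparison with WT these were Tet1, the 8 genes with the largest change in each direction among called genes with non-overlapping groups and a mean of at least 5 CPM in 1 group, and up to 4 called members of each list with the smallest adjusted p. Predicted genes and unnamed transcripts were left out of the first part. Stra8, Sycp3, Sycp1, Dazl, Ddx4, Pou5f1, Dppa3, Peg3, H19, Dlk1, Tet2 and Tet3 were always included. Tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives were the size factors of DESeq2 in the edgeR fit, DESeq2, limma-voom, no low-count filter, a mean of at least 5 CPM, the replicate number as a block, only the libraries of the groups compared, an absolute log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were voom with quality weights, the libraries HxD1, KO1 and KO3 left out together, a covariate from the meiotic list, and leaving out libraries in the list tests. Overlaps between comparisons were set beside 100 simulated data sets without change in any group.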

Results

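Gene expression was measured by RNA sequencing in Oct4-GFP-sorted primordial germ cells of female mouse embryos at stage E14.5. The series compared wild-type cells (WT) with cells carrying 3 kinds of Tet1 mutation, in 4 groups of 3 libraries. TET1 oxidizes 5-methylcytosine in DNA, HxD lacks this activity, V is described as stalling at the first product, 5-hydroxymethylcytosine, and KO is the knockout. The comparisons ask which transcripts depend on TET1 and whether the mutants differ from one another. Total counts were 28410605, 24243492 and 26314575 in the HxD libraries, 26591362, 25219140 and 22737470 in KO, 18471158, 29495313 and 28708605 in V, and 28323877, 20557016 and 24788687 in WT.

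Tet1 itself was at 91.4, 180.1 and 215.1 CPM in the WT libraries and at 130.7, 158.3 and 80.8 CPM in KO. It was at 227.0, 221.7 and 285.8 CPM in HxD and at 225.7, 197.0 and 192.0 CPM in V. None of the 3 differences from WT was called, with log2 fold changes of 0.59 ± 0.24 (SE) in HxD, -0.40 ± 0.24 in KO and 0.34 ± 0.24 in V (edgeR, adjusted p = 0.607, 0.484 and 0.709, n = 3). The counts cover the whole gene and the deleted part is not given in the sources used here, so Tet1 neither checks nor contradicts the KO labels. Tet2 and Tet3, the related dioxygenases, were not called in any comparison with WT.

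**Figure D1:**
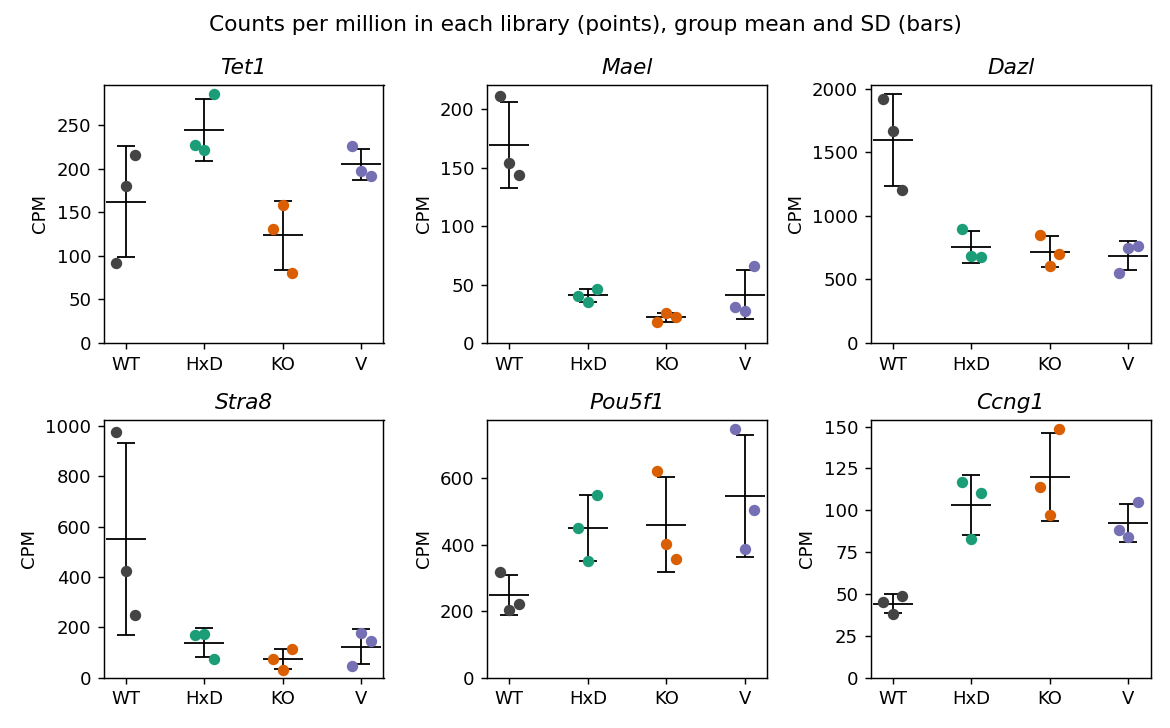
CPM of 6 genes in each of the 12 libraries (points; y axes are linear and start at 0), with the group mean and SD as bars. Mael and Dazl were lower and Ccng1 was higher in each mutant library than in each WT library, while the ranges of Tet1 in KO and WT overlapped.

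In HxD against WT, 5 of 16166 genes changed (edgeR, adjusted p under 0.05), 1 higher and 4 lower. Mael, which acts in transposon silencing in germ cells, fell from 169.5 ± 36.5 to 40.7 ± 5.71 CPM (log2 fold change -2.06 ± 0.28, adjusted p = 0.000607). Dazl, an RNA-binding protein that germ cells need to enter meiosis, fell from 1598 ± 363 to 753.2 ± 127.6 CPM (log2 -1.09 ± 0.19, adjusted p = 0.0197). Tex101, a germ cell surface protein gene, fell by 2.56 on the log2 scale (adjusted p = 0.0359), and Ccng1, a p53 target, rose from 44.2 ± 5.52 to 103.2 ± 18.05 CPM (log2 1.22 ± 0.21, adjusted p = 0.0153). Gm7972, a predicted gene outside the naming rule and named after its values were seen, had a log2 fold change of -1.60 (adjusted p = 0.0153).

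Of 33 tested germline genes that are methylated in somatic cells, 3 were lower in HxD and 30 were not called over all genes; adjusted over the list alone, 17 were lower and 1 higher. The median log2 fold change of that list was -0.91 (camera, adjusted p = 5.03e-26; adjusted p = 0.0282 with an estimated correlation). None of 55 tested meiotic genes was called over all genes and 14 were lower adjusted over the list alone, with a median of -0.89 (camera, adjusted p = 3.95e-26; 0.0282 as the adjusted p with an estimated correlation). Stra8, which drives meiotic entry, had a log2 fold change of -1.98 ± 0.43 (edgeR, adjusted p = 0.0928), and the synaptonemal complex gene Sycp3 one of -2.08 ± 0.45 (edgeR, adjusted p = 0.0838); without WT1 these were -1.27 and -1.15. The piRNA list had a median of -0.52 (camera, adjusted p = 1.14e-09; adjusted p = 0.0282 with an estimated correlation), with Mael as its 1 called member of 22; adjusted over the list alone, 4 were lower and 1 higher. The p53 and apoptosis list had a median of 0.39 over 20 genes (camera, adjusted p = 1.58e-07; adjusted p = 0.0130 with an estimated correlation), with Ccng1 called over all genes and 2 genes higher adjusted over the list alone. The 34 pluripotency and early germ cell genes had a median of 0.51 with none called over all genes and 13 higher adjusted over the list alone (camera, adjusted p = 9.27e-16; lost, at adjusted p = 0.0634, with an estimated correlation). The mitotic cell cycle list had a median of 0.05 with none of 33 genes called (camera, adjusted p = 0.0208; lost, at adjusted p = 0.509, with an estimated correlation). Neither imprinted list passed (camera, adjusted p = 0.123 for maternally and 0.435 for paternally expressed genes), and Peg3, H19 and Dlk1 were not called. Sycp1, Pou5f1, Ddx4 and Dppa3 were not called either (edgeR, log2 -1.71, 0.86, -0.48 and 0.21, adjusted p = 0.0592, 0.29, 0.612 and 0.955).

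The count of 5 depended on single libraries, being 2 without HxD2, 1 without HxD3, WT1 or WT2, 35 without WT3, 8 without KO3 and 10 without V1. It was 92 by DESeq2, and 6 with HxD1, KO1 and KO3 left out, a choice made after seeing how few genes they captured. At a mean of at least 5 CPM only Mael kept its call, with adjusted p values of 0.0586 for Dazl and Ccng1 and 0.174 for Tex101 (edgeR). Of the 4 called named genes, Mael stayed called with each of the 12 libraries left out in turn. The call was lost for Dazl without HxD2, HxD3, WT1 or WT2 (edgeR adjusted p up to 0.229), for Ccng1 without HxD1, HxD3, WT1 or WT2 (up to 0.105), and for Tex101 without any 1 HxD library, WT1 or WT2 (up to 0.643). Lower germline genes numbered 1 to 9 over these fits.

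In KO against WT, 197 genes changed (edgeR, adjusted p under 0.05), 117 higher and 80 lower; with the size factors of DESeq2 the split was 90 higher and 95 lower. Meiotic genes were lower: 12 of 55 were called over all genes and 27 adjusted over the list alone, and 43 were not called. Stra8 fell from 549.1 ± 381.0 to 73.5 ± 41.1 CPM (log2 -2.90 ± 0.45, adjusted p = 0.000907). Also lower were Gm4969 (Meiosin), the partner of STRA8 (log2 -2.95), the recombinase Dmc1 (-1.55) and the synaptonemal genes Sycp1 (-2.13) and Sycp3 (-2.08). The meiotic list had a median of -1.22 (camera, adjusted p = 1.83e-25; adjusted p = 0.0373 with an estimated correlation).

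Of the 33 germline genes methylated in somatic cells, 13 were lower and 1, Rhox6, was higher in KO, Rhox6 being named after its values were seen; adjusted over the list alone, 21 were lower and 2 higher. Mael fell to 21.8 ± 4.01 CPM (log2 -2.96 ± 0.29, adjusted p = 7.21e-07), and Tex101 (log2 -4.12), Taf7l (-3.12), Brdt (-2.60) and Dazl (-1.15) were lower. Ddx4 was not called (edgeR, log2 -0.58, adjusted p = 0.169). The list median was -0.97 (camera, adjusted p = 1.83e-25; adjusted p = 0.0373 with an estimated correlation). Of 22 piRNA and transposon silencing genes, Mael, Gpat2 (log2 -1.44), Tdrd1 (-2.11), Mov10l1 (-0.90) and Tdrd7 (-1.06) were lower, the last pair named after their values were seen, while Morc1, which silences transposons in germ cells, rose from 17.5 ± 6.66 to 65.6 ± 4.50 CPM (log2 1.91 ± 0.35, adjusted p = 0.00534). The piRNA list had a median of -0.60 (camera, adjusted p = 9.45e-09; adjusted p = 0.0373 with an estimated correlation), with 8 genes lower and 1 higher adjusted over the list alone.

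Of 34 pluripotency and early germ cell genes, 5 were higher in KO and 29 were not called; 20 were higher adjusted over the list alone. Sox2 rose from 221.4 ± 71.8 to 426.1 ± 35.0 CPM (log2 0.94 ± 0.20, adjusted p = 0.0156), and Esrrb, Ifitm3, Tfap2c and Nanog rose by 1.14, 1.13, 1.07 and 1.01 on the log2 scale, Nanog being named after its values were seen. Pou5f1, the gene whose reporter was used for the sort, was at 460.0 ± 141.5 CPM against 248.0 ± 61.2 in WT (log2 0.89 ± 0.23, adjusted p = 0.0519, not called). Dppa3 was not called either (edgeR, log2 0.38, adjusted p = 0.384). The list median was 0.70 (camera, adjusted p = 2.07e-17; adjusted p = 0.0475 with an estimated correlation). Of 20 p53 and apoptosis genes, 3 were higher: Ccng1 (log2 1.44), the cell cycle inhibitor Cdkn1a (0.85) and Gtse1 (0.81); 10 were higher adjusted over the list alone. That list had a median of 0.68 (camera, adjusted p = 4.20e-10; adjusted p = 0.00362 with an estimated correlation).

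Among imprinted genes, the paternally expressed Plagl1 rose from 119.2 ± 53.5 to 299.5 ± 19.8 CPM in KO (log2 1.33 ± 0.24, adjusted p = 0.00455), and the maternally expressed Phlda2 rose by 0.94 on the log2 scale (adjusted p = 0.0227). These were the 1 called member of 29 and the 1 of 26. Adjusted over the list alone, 5 paternally expressed genes were higher, and of the maternally expressed genes 1 was higher and 1 lower. Peg3, H19 and Dlk1 were not called. The paternally expressed list passed the test with a median of 0.41 (camera, adjusted p = 0.0312; lost, at adjusted p = 0.123, with an estimated correlation), and the maternally expressed list did not (camera, adjusted p = 0.513). Uhrf1, which directs DNA methylation to replicating DNA, fell from 98.1 ± 17.99 to 48.5 ± 10.4 CPM (log2 -1.02 ± 0.23, adjusted p = 0.0223), while the repair genes Lig3 and Gadd45a rose by 0.86 and 1.22; their list of 30 DNA methylation and demethylation genes did not pass (camera, adjusted p = 0.136), with 4 higher and 1 lower adjusted over the list alone. The retinoic acid and BMP list had a median of -0.19 (camera, adjusted p = 0.00716; lost, at adjusted p = 0.0940, with an estimated correlation) and the mitotic list one of 0.16 (camera, adjusted p = 0.0166; lost, at adjusted p = 0.552, with an estimated correlation).

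The largest changes by the naming rule were Car12 (log2 2.39), Zfp296 (2.32), Morc1, Fam222a (1.63), Gstm1 (1.59), Adrb3 (1.55) and B4galnt3 (from 16.3 ± 6.24 to 45.9 ± 8.20 CPM) among the higher genes. Gmnc had 0 counts in the 3 WT libraries and in HxD1, and a mean of 8.96 CPM in KO. Against a floor of 3 counts per library this was 74.0-fold, and 37.0-fold without KO1. The floor covers counting error and not lost molecules, so these folds are not lower bounds. The call of Gmnc was lost without KO1, WT1 or WT2 (edgeR adjusted p up to 0.0879). Lower genes were Tex101, Dmrta2 (-3.84), Col27a1 (-4.73), Tsc22d3 (-3.31), Taf7l, Mael, Btbd18 (-2.93) and Dhrs7 (-2.90, with an adjusted p of 0.142 by DESeq2). Col27a1 was at 0 CPM in KO1 and KO3, Dmrta2 in KO3 and Dhrs7 in KO1, where lost molecules may enlarge the change. In KO2 they were at 1.45, 4.76 and 1.57 CPM. The call of Col27a1 was lost without any 1 of 8 libraries (edgeR adjusted p up to 0.197), and that of Dmrta2 without KO1 or WT1 (up to 0.0973). Of 189 called genes with a known chromosome, 22 were on the X, where 3.93% of 560 genes were called against 1.15% of the other genes (Fisher's exact test, two-sided, odds ratio 3.51, adjusted p = 4.18e-05 over the chromosomes). On the X, 15 were higher and 7 lower, and X-linked genes with a mean of at least 5 CPM had a median log2 fold change of -0.0059. Fisher's test takes genes as independent and holds no spread between libraries. It was not repeated with libraries left out. Genes within 20 Mb of Tet1 held 4 of the 189 calls (Fisher's exact test, p = 0.792).

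By limma-voom the calls of Car12, Cdkn1a, Dhrs7, Gadd45a and Zfp296 were lost (adjusted p = 0.0712 to 0.202), and at a mean of at least 5 CPM those of Adrb3, Cdkn1a, Dhrs7, Esrrb, Gadd45a, Gtse1 and Tfap2c (edgeR, adjusted p up to 0.0721). The KO count was 77 without KO2, 88 without KO3, 31 without WT1, 77 without WT2 and 357 without WT3, and 630 by DESeq2. With HxD1, KO1 and KO3 left out, when KO is 1 library assumed to vary like the other groups, it was 30, with 5 meiotic, 7 germline and 1 piRNA gene lower and 1 pluripotency and 0 p53 genes higher. Of 37 called named genes, 15 stayed called with each of the 12 libraries left out in turn, among them Mael, Stra8, Sycp1, Dazl, Tex101, Morc1 and Plagl1. Named calls were lost for 21 genes without WT1, 16 without WT2, 15 without KO2, 14 without KO3, 8 without KO1, 4 without V2 or V3, 3 without HxD3, 2 without HxD2 or WT3 and 1 without V1. Among them were Sox2 (edgeR adjusted p up to 0.116), Sycp3 (up to 0.340), Uhrf1 (up to 0.1096), Phlda2 (up to 0.151), Gadd45a (up to 0.291), Cdkn1a (up to 0.143, without 7 of the libraries) and Gtse1 (up to 0.270, without 9). Without 1 library the log2 fold change went to -1.15 for Sycp3 (WT1), 0.72 for Gadd45a (KO3) and -11.36 for Col27a1 (KO2). Member counts ranged over these fits from 5 to 15 for lower meiotic genes, 8 to 16 for lower germline genes, 3 to 5 for lower piRNA genes, 1 to 6 for higher p53 genes, and 0 to 15 for higher pluripotency genes, with 5 meiotic genes left without WT1 and 0 pluripotency genes without WT2. The p53 count was 1 without any 1 KO library, V3, WT1 or WT2.

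**Figure D2:**
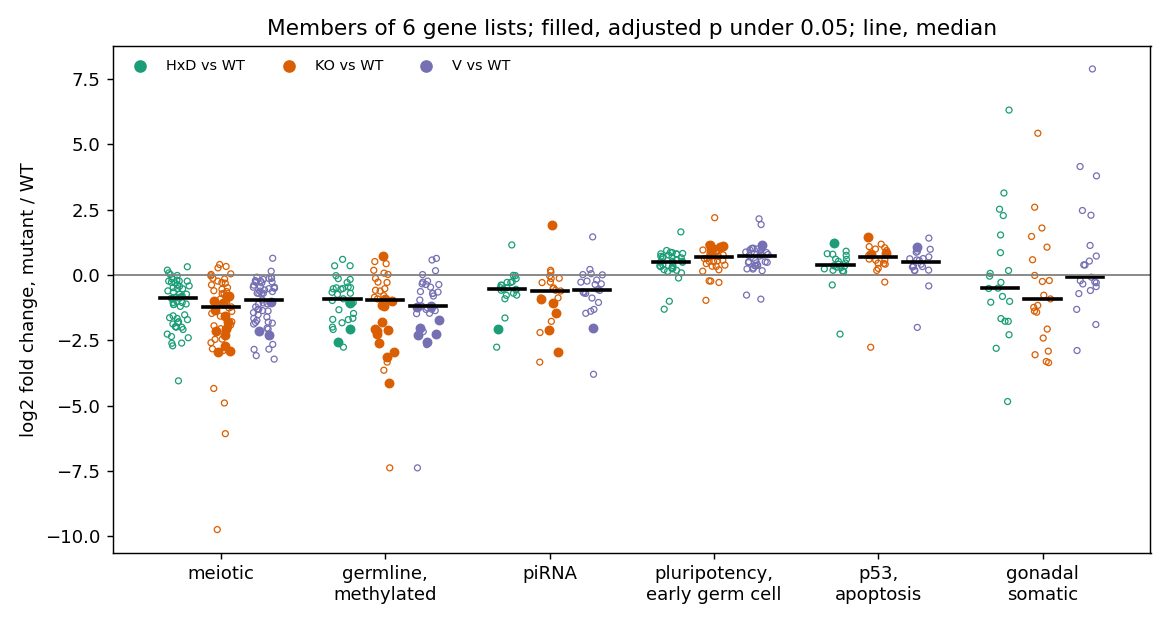
Log2 fold changes (y axis) of the tested members of 6 gene lists in each mutant against WT; filled points have an adjusted p under 0.05 and lines are medians. Medians of the meiotic list were -0.89, -1.22 and -0.96 in HxD, KO and V, and those of the pluripotency list were 0.51, 0.70 and 0.74.

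In V against WT, 25 genes changed (edgeR, adjusted p under 0.05), 11 higher and 14 lower; with the size factors of DESeq2 the split was 10 higher and 22 lower. Mael fell to 41.3 ± 21.03 CPM (log2 -2.03 ± 0.28, adjusted p = 0.000755) and Dazl to 685.7 ± 115.0 CPM (log2 -1.22 ± 0.19, adjusted p = 0.00312). Of the germline genes methylated in somatic cells, 7 of 33 were lower, Mael, Dazl, Sycp1, Taf7l, Tex101, Brdt and Tuba3a, and adjusted over the list alone 18 were lower and 2 higher. The list median was -1.19 (camera, adjusted p = 7.69e-26; adjusted p = 0.0370 with an estimated correlation). Of 55 meiotic genes, Stra8 (log2 -2.16), Sycp1 (-2.28) and Tex15 (-1.02) were lower and 52 were not called, with 15 lower adjusted over the list alone. The meiotic median was -0.96 (camera, adjusted p = 2.32e-22; adjusted p = 0.0370 with an estimated correlation). The piRNA list had a median of -0.57 (camera, adjusted p = 4.47e-09; adjusted p = 0.0370 with an estimated correlation), with 6 genes lower and 1 higher adjusted over the list alone.

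Pou5f1 rose in V from 248.0 ± 61.2 to 546.1 ± 183.5 CPM (log2 1.14 ± 0.23, adjusted p = 0.0397), the 1 called member of 34 pluripotency and early germ cell genes, of which 16 were higher adjusted over the list alone. Their median was 0.74 (camera, adjusted p = 1.98e-19; adjusted p = 0.0387 with an estimated correlation). Ccng1 rose by 1.06 on the log2 scale, with 5 p53 genes higher adjusted over the list alone, and the p53 list had a median of 0.49 (camera, adjusted p = 2.57e-07; adjusted p = 0.0121 with an estimated correlation). Other genes that rose were Hmgn5, Socs2, Wsb2, Slc25a13, Vim and Nmt1, by 0.97 to 1.37, and Lamb2 (-1.49) and Tsc22d3 (-2.27) were lower. The mitotic list had a median of 0.13 (camera, adjusted p = 0.000866; lost, at adjusted p = 0.462, with an estimated correlation). Neither imprinted list passed (camera, adjusted p = 0.978 and 0.419 for maternally and paternally expressed genes), and Peg3, H19 and Dlk1 were not called in V. Sycp3, Ddx4 and Dppa3 were not called either (edgeR, log2 -1.36, -0.65 and 0.47, adjusted p = 0.234, 0.213 and 0.393). By limma-voom 9 of the 19 called named genes lost their call (adjusted p of at least 0.0690), Taf7l, Tex101, Brdt, Ccng1, Hmgn5, Socs2, Nmt1, Lamb2 and Tsc22d3, and by DESeq2 Stra8 did (adjusted p = 0.0565). At a mean of at least 5 CPM 15 of the 19 did, leaving Mael, Dazl, Sycp1 and Tuba3a. The V count was 2 without V1, 14 without V3, 10 without WT1, 5 without WT2, 110 without WT3 and 43 without KO3, and 273 by DESeq2. It was 16 with HxD1, KO1 and KO3 left out, and of 19 called named genes Mael stayed called with each of the 12 libraries left out in turn. The other 18 named calls were lost without V1, 15 of them without WT2, 12 without WT1, 11 without V3, 5 without V2 and at most 3 without any 1 other library. Among these were Dazl (edgeR adjusted p up to 0.134), Sycp1 (0.0505), Stra8 (up to 0.334) and Pou5f1 (up to 0.422). Over these fits lower germline genes numbered 1 to 8 and lower meiotic genes 0 to 9, and the log2 fold change went to -1.48 for Tex101 without WT1 and 0.91 for Hmgn5 without V1.

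Markers of other cell types that a sort could hold did not pass in any mutant against WT. Few of them reached a mean of 5 CPM: 2 of 21 tested gonadal, 2 of 7 Sertoli and Leydig, 0 of 12 blood and 3 of 9 endothelial genes. Their medians therefore rest mostly on genes of few counts, and these tests exclude little. The gonadal supporting and interstitial list had medians of -0.50, -0.91 and -0.08 in HxD, KO and V (camera, adjusted p = 0.435, 0.372 and 0.667). Sertoli and Leydig markers had medians of 0.76, 0.24 and 0.64 (adjusted p = 0.123, 0.709 and 0.402), blood markers -2.86, -2.23 and -0.68 (0.127, 0.458 and 0.978) and endothelial markers 0.70, 0.44 and 0.17 (0.345, 0.936 and 0.657). The mitochondrial list gave 0.298, 0.0951 and 0.377, and the dissociation list 0.986, 0.800 and 0.117. Oocyte genes gave 0.123, 0.372 and 0.377, male germ cell fate genes 0.435, 0.513 and 0.657, and Hox and other Polycomb-regulated genes 0.384, 0.458 and 0.978. The retinoic acid and BMP list gave 0.0507 in HxD and 0.402 in V, and the DNA methylation list 0.435 and 0.491. In V the gonadal and blood medians (-0.08 and -0.68) had the opposite sign to their tests. Medians and means differed in sign for Sertoli and Leydig markers in KO, endothelial markers in KO and V, and gonadal markers and maternally expressed imprinted genes in V. Blood markers stood apart in single libraries: their summed CPM over 25 genes was 85.1 in WT1, 43.1 in V1 and 38.4 in KO3, against 7.39 in WT2, 6.17 in WT3 and 2.10 to 18.2 in the other mutant libraries. Hbb-y, an embryonic globin gene, had 670 counts in KO3, 7 in V1 and 0 in the other 10 libraries. WT1 was also the WT library with the highest germline and meiotic medians. Without WT1 the germline medians were -0.57, -0.80 and -0.61 in HxD, KO and V and the meiotic medians -0.62, -0.82 and -0.48, and each list still passed at the preset correlation (camera, adjusted p at most 1.42e-11). This was not repeated with an estimated correlation. Other medians that 1 library moved by over 1.5 times were those of pluripotency and p53 genes in HxD without WT3 (0.79 and 0.59), of piRNA genes in V without V1 (-0.36), and of paternally expressed imprinted genes in KO without KO1 (0.21). The call of that imprinted list was lost without KO1, WT1 or WT3 (camera, adjusted p = 0.0950, 0.0730 and 0.0672). The retinoic acid and BMP median in KO was -0.11 without WT1. The mitotic medians were 0.03, 0.07 and 0.11 in HxD, KO and V without WT1, where no call held (camera, adjusted p = 0.533, 0.386 and 0.117), and 0.18, 0.26 and 0.29 without WT3. They were 0.10 in HxD without HxD3, 0.25 in V without V2, and 0.03 and 0.10 in HxD and KO without WT2. The mitotic call was also lost in HxD without HxD1 or WT2 and in KO without WT2 (camera, adjusted p = 0.171, 0.106 and 0.0606). The libraries that captured the fewest genes were in mutant groups, HxD1, KO1, KO3 and V2. The lists also varied within WT: the germline median differed from the WT mean by 0.34 in WT1, -0.11 in WT2 and -0.23 in WT3, and lay between -1.26 and -0.51 in the 9 mutant libraries.

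**Figure D3:**
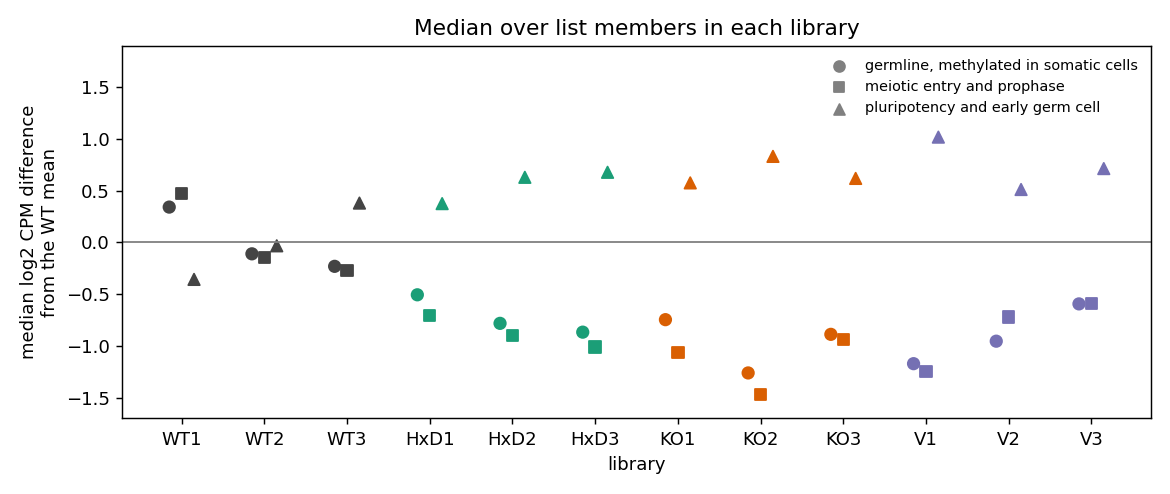
Median log2 CPM difference from the WT mean (y axis) over the members of 3 gene lists in each of the 12 libraries (x axis). The germline and meiotic medians of each mutant library lie below those of the 3 WT libraries, while the pluripotency median of WT3, 0.38, is as high as that of HxD1.

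The changed genes overlapped. All 5 genes changed in HxD, Mael, Dazl, Tex101, Gm7972 and Ccng1, were also changed in KO and in V, and 21 of the 25 genes changed in V were changed in KO. KO and V shared 9 higher and 12 lower genes, where independent lists give 0.0796 and 0.0693 and simulations without change gave at most 1 and 0. The simulated comparisons called at most 4 genes each, so they give no bound for lists of these sizes. Comparisons share the WT libraries, so part of this excess may come from them. Over 10402 genes the log2 fold changes correlated at 0.74 between HxD and KO, 0.75 between HxD and V and 0.73 between KO and V, against means of 0.50 in each pair of simulated comparisons. The covariances were 0.201, 0.173 and 0.220 against simulated means of 0.0966, 0.0967 and 0.0963, differences of 0.104, 0.0760 and 0.123. The 3 WT libraries are too few to split.

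Direct tests between mutants called 0 genes in HxD vs KO, V vs KO and V vs HxD (edgeR), with 514, 747 and 326 genes at an unadjusted p under 0.05 where chance gives 808.3. All 3 counts lie below the number that chance gives, so these tests may be conservative. The 0 calls therefore do not show that the mutants are alike. DESeq2 called 34, 22 and 19 and limma-voom 0 in each, and with 1 library left out edgeR called at most 3 genes (HxD vs KO and V vs KO without KO2). Some lists differed by camera at the preset correlation. Germline and meiotic genes were higher in HxD than in KO by medians of 0.20 and 0.27 (adjusted p = 0.00691 and 0.00759), and meiotic genes were higher in V than in KO by 0.32 (adjusted p = 0.0171). None of these held with an estimated correlation (adjusted p = 0.595, 0.595 and 0.711).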

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

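The splits, the covariate for stage and the fit without HxD1 had their outcomes stated before they were run; the tests of somatic cells, of library complexity, of a larger KO effect and of genes at 0 were chosen after the results were seen.

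Lists were taken up here where the change against WT differed between 2 mutants by the direct list test (camera). In HxD vs KO these were the meiotic (adjusted p = 0.00759), germline (0.00691), pluripotency (0.0110), p53 (0.0110) and paternally expressed imprinted lists (0.0320). In V vs KO they were the meiotic (0.0171), retinoic acid and BMP (0.0171), dissociation and heat shock (0.0283) and mitochondrial lists (0.000399), and in V vs HxD the dissociation (0.0419) and mitochondrial lists (0.00858). None held with an estimated correlation, where the adjusted p ranged from 0.296 to 0.918.

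Germline and meiotic lists were lower in all 3 mutants, and the pluripotency list was higher, a call that in HxD was lost with an estimated correlation (adjusted p = 0.0634). A larger share of somatic cells in the mutant sorts would dilute all germ cell transcripts, although the Oct4-GFP sort selects against them. Summed CPM of 29 gonadal markers was 122.8 to 179.7 in the mutant libraries and 153.0 to 190.9 in WT, but Sertoli and Leydig markers (20.8 to 60.5 against 24.6 to 30.2 in WT) and endothelial markers (28.8 to 59.2 against 15.2 to 44.6) each lay above all 3 WT libraries in 7 of the 9 mutant libraries. The Sertoli and Leydig list shares 1 gene, Nr0b1, with the pluripotency list, and only 2 of its 7 tested genes reached 5 CPM. Its sum can therefore rest on few genes and need not reflect somatic cells. Dilution as the only cause is argued against by the pluripotency and early germ cell list, which it would lower. The smallest of its 3 medians was 0.51 (in HxD, and 0.37 there without WT1). Between libraries, the list differed from WT by 0.56 in HxD, 0.68 in KO and 0.75 in V, with 95% intervals (Welch) of -0.22 to 1.35, -0.13 to 1.48 and -0.01 to 1.51. These include 0, so they do not show a rise. HxD1 (0.38) lay no higher than WT3 (0.38), while the lowest KO and V libraries (0.58 and 0.51) lay above WT3. All 3 intervals lie above -0.4, the bound set for dilution. That bound was applied to them after the values per library were seen. Within WT this list ran against the meiotic list, at -0.36 and 0.47 in WT1 and 0.38 and -0.27 in WT3. WT3 also held Y-linked transcripts (227 counts of Eif2s3y), and WT1 had the highest summed CPM of blood markers (85.1). What set these WT libraries apart was not tested. If it was stage, a stage difference between groups, left open below, could raise the pluripotency list and hide some dilution. Loss of rare molecules in mutant libraries is argued against by the 5 mutant libraries with at most 9.94% of low genes at 0, where the germline median closest to the WT mean was still -0.59. These were HxD2, HxD3, KO2, V1 and V3. For KO the argument rests on KO2 alone, whose germline median was -1.26, against -0.75 in KO1 and -0.89 in KO3. A later stage of the WT embryos stays open: with the meiotic mean as covariate, the KO difference of the 26 germline genes outside the meiotic list went from -0.92 ± 0.20 (SE) to -0.38 ± 0.32, that of HxD from -0.64 ± 0.20 to -0.27 ± 0.26, and that of V from -0.90 ± 0.20 to -0.52 ± 0.26, the V value lying just past 2 SE below 0. The covariate lies 73.3% between groups and the mutation may itself change it, so stage and genotype cannot be told apart here; an effect of TET1 on these genes is the biological explanation that the design names.

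KO had more called genes than HxD. Whether the low-complexity library HxD1 hides changes stays open. The count without it was 4 genes, but 2 libraries give less power, so this count cannot decide. Leaving out 1 KO library left 77 to 153 KO calls. Without HxD1 the HxD meiotic median went from -0.89 to -1.08 and the germline median from -0.91 to -0.89. With quality weights (0.33 for HxD1), voom called 22 genes in HxD and 112 in KO, against 15 and 187 without weights. A larger effect of KO on the same genes stays open: the germline median was 0.20 higher in HxD than in KO, with an interval over resampled genes of 0.07 to 0.57, which holds no spread between libraries. With 1 library left out it ranged from 0.09 (without HxD1) to 0.30 (without KO1). The counts may therefore differ through the threshold, through HxD1 or through the size of the effect. These cannot be told apart, since 0 genes passed the direct test and the list test was lost with an estimated correlation.

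A few genes had 0 counts in all 3 libraries of a group and at least 10 in each of the other 9, Was and Ttc21a in WT and Popdc3 and 2510003B16Rik in KO, chosen after their values were seen. Loss of rare molecules was tested in 2 ways that read differently. Of the 216 triples of libraries that are no group, 31 held at least as many such genes, up to 38 in HxD1, KO1 and KO3. Among triples of like expected loss, 2 of 45 held as many as WT and 0 of 54 as many as KO. With 2 genes in each group neither form decides, so loss of molecules and a difference between the mouse lines cannot be told apart.

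With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many changed genes as in the real split were given by 1 split, the real one, for HxD vs WT (5 genes, highest other 1), KO vs WT (197, highest other 1) and V vs WT (25, highest other 0). All 10 splits gave at least the 0 genes of HxD vs KO (highest other 5), V vs KO (1) and V vs HxD (0).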

How the results depend on the processing

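Chosen after seeing the data were quality weights, leaving out HxD1, KO1 and KO3, the meiotic covariate, leave-one-out of list tests and DESeq2 for overlaps. For HxD, KO and V against WT, changed genes numbered 92, 630 and 273 by DESeq2, 15, 187 and 20 by limma-voom, and 71, 464 and 176 with no low-count filter. They numbered 1, 137 and 5 at a mean of at least 5 CPM, 20, 189 and 20 from only the groups compared, and 5, 129 and 22 at an absolute log2 fold change of at least 1. Quality weights gave 22, 112 and 145, HxD1, KO1 and KO3 left out 6, 30 and 16, and the covariate 0, 0 and 0. Similar counts hid different genes: of the 197 and 25 genes called in KO and V, limma-voom shared 150 and 12 and the fit of only the groups compared 153 and 13. The 5 CPM filter gave fewer calls that were mostly the same genes, with 131 of 137 shared in KO and 5 of 5 in V. With 1 library left out the ranges were 1 to 35, 31 to 357 and 2 to 110.

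With the replicate number as a block the counts were 22, 285 and 73, for HxD vs KO 2 and for V vs KO 1, and 1 list was called in V vs HxD. Same-numbered libraries deviated together by correlations of -0.1498 to 0.1088 over 18 pairs, and 3 of 12 libraries correlated best with their own number. Differently numbered libraries of different groups gave -0.1371 to 0.1552. Over the 10402 genes used, these correlations show no sharing by number. They cannot exclude a batch or litter that moved only part of the genes. The counts against WT rose with the block, so this stays open.

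Between mutants, HxD vs KO gave 1 gene with the size factors, 34 by DESeq2, 10 with no filter, 1 from only these groups, 3 with quality weights and 0 to 3 with 1 library left out. V vs KO gave 22 by DESeq2, 5 with no filter, 1 from only these groups and 0 to 3 with 1 library left out, and V vs HxD gave 19, 1 with no filter, 1 with quality weights and 0 to 1. Lists called with an estimated correlation were 5 of 8 in KO vs WT and 0 in each comparison of mutants. With 1 library left out, 1 to 6 lists were called in HxD vs KO, 2 to 7 in V vs KO and 0 to 5 in V vs HxD. With HxD1, KO1 and KO3 left out there were 3 in HxD vs KO and 4 in V vs HxD. Against WT, the meiotic, germline, piRNA, pluripotency and p53 lists passed at the preset correlation with each of the 12 libraries left out. In KO the estimated correlations of these lists were 0.24, 0.29, 0.12, 0.27 and 0.010, in that order, against the preset 0.01. A pass at the preset therefore shows little for all but the p53 list. The estimated correlation was not used with libraries left out. Shared genes by DESeq2 were 47 higher and 24 lower for HxD and KO, 43 and 19 for HxD and V, and 102 and 60 for KO and V, and 5 higher for KO and V at an absolute log2 fold change of at least 1.

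With the covariate, 15 of the 197 genes called in KO turned in direction, and 0 of the 5 in HxD and 0 of the 25 in V. Named log2 fold changes in KO turned to -0.13 for Esrrb, 0.0062 for Stra8, 0.63 for Sycp3 and -0.036 for Tfap2c. Stra8 is itself among the genes of the covariate. The mitochondrial median in V vs HxD, -0.31, turned to 0.02 without HxD3 and 0.10 without V2, and ranged from -0.94 (without V3) to 0.10. Of 1319 alternatives of the 60 called named results, 981 kept direction and call, 334 lost the call and 4 turned; among the alternatives of the 27 uncalled results, 37 gave a call. The causes of these shifts were not tested, beyond fewer genes or libraries entering some fits. The 5 CPM filter removes genes of few counts. The share of low genes at 0 did not follow depth, at 9.94% in V1 (18471158 total counts) and 24.5% in V2 (29495313).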

Other observations

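The X-linked genes called in KO were followed further, chosen after the result was seen. The p-values and intervals below take genes as independent and hold no spread between libraries. Xist, an X-linked transcript, varied from 16 counts in HxD2 to 518 in KO3. Leaving out the members of all fixed lists, 19 of 551 X-linked genes were called, 3.45% against 0.941% of the other genes (Fisher's exact test, two-sided, odds ratio 3.76, 95% interval 2.18 to 6.16, unadjusted p = 4.15e-06). Higher genes included Atrx (log2 0.92), Rlim (0.71), Tfe3 (0.98), Porcn (0.85), Klf8 (1.06), Pls3 (1.26), Hmgn5 (1.10) and Pdha1 (0.69). Lower genes included Hdac6 (-1.25), Scml2 (-0.97), Trap1a (-1.45) and Tsc22d3 (-3.31). In V, 3 of 551 were called with the list members left out (odds ratio 7.03, 95% interval 1.26 to 26.7, unadjusted p = 0.0140) and 4 of 560 over all genes (odds ratio 4.97, adjusted p = 0.256 over the chromosomes by Fisher's exact test), and in HxD 0, so a difference between the mutants was not tested.

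Y-linked transcripts were present in 5 libraries labelled female. WT3 had 227 counts of Eif2s3y, 49 of Ddx3y and 1 of Uty, KO3 had 62 of Kdm5d, V1 had 10 of Usp9y, and KO2 and HxD2 had 1 of Ddx3y and of Kdm5d, while Eif2s3y was at 0 in the other 11 libraries. WT3 was also the WT library with the lowest germline and meiotic medians (-0.23 and -0.27 from the WT mean) and the highest pluripotency median (0.38), and without it 35, 357 and 110 genes were called in HxD, KO and V. Whether these go together was not tested.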
